A study of Candida albicans with 12 samples.

How the data were processed

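Polyadenylated RNA of Candida albicans was measured by PAT-seq, a method that sequences the 3′ ends of polyadenylated transcripts, in 12 libraries. The wild-type strain SC5314 was grown in 4 ml of RPMI buffered with MOPS to pH 7.0 at 37 °C from a starting optical density (600 nm) of 0.1, with gladiolin at 16 µg/ml or with 0.08% DMSO as the solvent control. RNA was taken at 1, 3 and 8 h by hot phenol extraction, with 2 libraries per treatment and time, all per the labels' protocols. The design text of the series speaks of independent experiments, but no label says which cultures the numbered replicates came from, so the p-values measure the spread between these libraries.

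The authors deposited 1 table of read counts per gene for all 12 libraries, 6219 genes in all, with whole numbers that sum to a different total in each library. The deposited counts are raw, since no column has been scaled to a common total. The submitters' processing notes name the aligner STAR. Its version, the counting program, the genome build and the gene annotation are not given in the sources used here, and no coordinates are printed for that reason. Gene symbols were taken from the table itself, which pairs 2794 of its systematic identifiers with a symbol. Of those symbols 2770 also occur in the RefSeq gene table of assembly ASM18296v3, which was used only for this check. Every column could be assigned to 1 library by its name, leaving 0 without a sample.

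Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which kept 4480 genes and removed 1739 that hold 0.246% of the counts. Libraries were scaled with TMM factors, and a quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries together. It left 6 residual degrees of freedom, with a prior of 8.77 degrees of freedom and a common biological coefficient of variation of 0.161. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over the 4480 genes. Gladiolin was compared with DMSO at each time, the gladiolin responses at 1 and 3 h and at 3 and 8 h were compared by interaction contrasts, and the DMSO libraries were compared between successive times. Log2 fold changes are those of the edgeR fit with its default prior count, while log2 CPM values use a prior count of 2. Standard errors were computed from each log2 fold change and its F statistic. Levels are TMM-normalised CPM, as mean ± SD of the 2 libraries of a group.

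Before the data were examined, 31 gene lists and the rule for the genes named in the text were fixed. The lists were tested with camera from limma 3.58.1 on log2 CPM, with the preset correlation between genes of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of each comparison. Of the lists 30 had the required 3 tested members. The list of mitochondrially encoded genes had none, because at most 9 counts per library fell on those genes. One member fixed for the hyphal lists, EED1, is not present under that symbol in the table. The lists for ribosome biogenesis, mitochondrial import, the mitochondrial ribosome and the proteasome were drawn in part by name prefix. Besides genes of the named process they hold 12, 1, 1 and 3 tested symbols of other or uncertain function. The genes named for each gladiolin comparison were the 6 with the largest rise and the 6 with the largest fall among called genes with a mean of at least 10 CPM, both gladiolin libraries on the same side of both DMSO libraries and a gene symbol. Added to these were 10 fixed genes of morphogenesis and respiration, and the 2 most changed called members of each list that passed the test, in the direction of that list. For DMSO over time only the 10 fixed genes are named. The rule gives 71 distinct genes.

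Replicates were compared before use. The counts of the replicate pairs differed by more than sampling noise in each group, with a chi-square per degree of freedom of 3.15 to 13.4, and the Pearson correlation of their log2 CPM was 0.967 to 0.989, so no pair was treated as a single library. Totals ran from 927637 to 3632697 counts per library, and low counts limit the precision of sparsely counted genes. PCR copies were not separated from original molecules in the deposited counts as far as the labels say, so intervals computed from counts cover counting error only.

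The test was checked on simulated counts for the 4480 genes, drawn from each gene's mean over all 12 libraries and the scaled library totals. In 1 group 200 genes were changed by a known fold. All other genes had the same level in each group, so real differences between groups were not copied. At 1 h it recovered 50% of 2-fold and 92% of 4-fold changes with 10 false calls. At 3 h the shares were 35% and 85% with 3 false calls, and at 8 h 46% and 83% with 12. For the interaction of 1 and 3 h they were 18% and 70% with 7 false calls, and for that of 3 and 8 h 12% and 56% with 8. For DMSO from 1 to 3 h they were 46% and 92% with 10 false calls, and from 3 to 8 h 42% and 84% with 11. For camera, a simulated shift of 1 log2 unit in 1 list was called, and 0 of the 28 lists without shared genes were. Genes were drawn independently there, so this check cannot show how often correlated genes give false list calls.

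Alternatives tried were RLE factors and library size alone in place of TMM, DESeq2 1.42.0 in place of edgeR, no filter and a filter of at least 50 counts in each library of 1 group, the replicate number as a block, a fit of only the groups compared, an added 2-fold threshold, the estimated correlation in camera, and leaving out each library in turn. Chosen after the data were seen were thinning of all libraries to the smallest total of 927637 counts, a fit of only the 1233 genes with a mean of at least 100 CPM and list tests without the symbols of other or uncertain function. Members of a list are called abundantly counted at or above that mean and sparsely counted below it. Bootstrap intervals of medians over genes are 95% percentile intervals from 10000 draws and describe the spread over genes, not over libraries. The counts do not separate alternative polyadenylation sites, and tail lengths were not analysed here.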

Results

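The data describe the polyadenylated transcripts of Candida albicans, a yeast that grows as hyphae in warm serum-like media, during its first hours in RPMI at 37 °C with or without gladiolin, a macrolide polyketide made by the bacterium Burkholderia gladioli. The title of the series concerns the switch between hyphae and yeast cells under gladiolin. Libraries were made at 1, 3 and 8 h from cells given 16 µg/ml gladiolin or the solvent DMSO, with n = 2 libraries in each of the 6 groups. The totals at 1 h were 1765048 and 3585677 counts for DMSO and 3460733 and 3632697 for gladiolin. At 3 h they were 1034292 and 1703833 for DMSO and 1583689 and 1466521 for gladiolin. At 8 h they were 1379842 and 1368659 for DMSO and 927637 and 1584078 for gladiolin. Adjusted p-values are from edgeR's quasi-likelihood test for genes and from camera for gene lists, with Benjamini-Hochberg adjustment. A multidimensional scaling used distances between libraries from the genes that differed most in each pair. Its first 2 dimensions held 30.2% and 26.3% of the variation in those distances.

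The first comparison asked what gladiolin changed within 1 h. Transcripts for glucose uptake and glycolysis rose most. HGT6 (orf19.2020), of the HGT family of glucose transporters, went from 53.9 ± 12.9 CPM in DMSO to 1554 ± 96.1 CPM in gladiolin (SD, n = 2 each), a log2 fold change of 4.87 ± 0.23 (SE, adjusted p = 3.34e-09). HGT7 (orf19.2023), a neighbour in the same family, went from 525 ± 129 to 12153 ± 194 CPM. TYE7 (orf19.4941), a transcriptional activator of glycolytic genes, rose by 4.66 ± 0.26 on the log2 scale (adjusted p = 9.65e-09), and PDC11 (orf19.2877), which encodes pyruvate decarboxylase, by 4.12 ± 0.26 (adjusted p = 2.10e-08). Of the 20 genes of the glycolysis and fermentation list 19 rose and 0 fell, with 19 also when adjusted over the list alone. The list had a median log2 fold change of 2.23 (camera adjusted p = 1.68e-22), and adjusted p = 0.0250 with an estimated correlation. Of the 18 hexose transporter and glucose sensing genes 9 rose and 2 fell, or 10 and 2 adjusted over the list alone (median 0.70, camera adjusted p = 0.00899, adjusted p = 0.185 with an estimated correlation). HGT6 and HGT7 are close relatives, and counting may have split shared reads between them.

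The lists for histones and S phase and for ergosterol were also called higher at 1 h, although most ergosterol genes were not called. RNR22, a ribonucleotide reductase subunit, rose by 4.09 ± 0.44 (log2, adjusted p = 9.27e-06), and the histone H2A gene HTA2 by 1.57 ± 0.32 (adjusted p = 0.00218). Of the 21 genes for histones and S phase 12 rose and 0 fell, the same counts as adjusted over the list alone (median 0.87, camera adjusted p = 2.83e-06, adjusted p = 0.153 with an estimated correlation). The histone genes have near-identical copies, so their counts may be shared. ERG251, which encodes a C-4 sterol methyl oxidase, rose by 3.22 ± 0.19 (adjusted p = 1.27e-08), and ERG1, which encodes squalene epoxidase, by 2.83 ± 0.50 (adjusted p = 0.000880). Of the 24 ergosterol genes 7 rose and 2 fell, or 9 and 2 adjusted over the list alone (median 0.29, camera adjusted p = 0.0284, adjusted p = 0.148 with an estimated correlation). The median of this list was -0.10 when libraries were scaled by their totals alone, a scaling that moved the median of all 4480 genes from -0.05 to -0.45.

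The 6 largest rises under the rule for named genes included 3 genes outside those lists. YHB1, the nitric oxide-detoxifying flavohaemoglobin, rose by 4.57 ± 0.26 (log2, adjusted p = 9.65e-09). PGA10, a CFEM protein of haem uptake, rose by 4.51 ± 0.40 (adjusted p = 1.12e-06), and CDR4, an ABC transporter, by 4.37 ± 0.26 (adjusted p = 1.22e-08). PGA10 belongs to a family with RBT5, PGA7, CSA1 and CSA2, so reads may be shared. AOX2, an alternative oxidase of the respiratory chain, rose by 3.21 ± 0.78 (adjusted p = 0.00785) on few reads, with 2 and 3 counts in the DMSO libraries and 21 and 29 in the gladiolin libraries. ICL1, which encodes isocitrate lyase, was not called (0.33 ± 0.23, adjusted p = 0.333).

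Morphogenesis genes moved in different directions at 1 h. NRG1 (orf19.7150), a repressor of hyphal growth, rose from 44.1 ± 3.14 to 295.2 ± 6.74 CPM, a log2 fold change of 2.73 ± 0.18 (adjusted p = 3.51e-08). ALS3 (orf19.1816), a hyphal adhesin, fell from 436.4 ± 34.9 to 100.5 ± 0.299 CPM, a log2 fold change of -2.12 ± 0.25 (adjusted p = 2.62e-05). ECE1 (orf19.3374), the gene for the precursor of the toxin candidalysin, fell from 2867 ± 316 to 1027 ± 4.86 CPM, a change of -1.48 ± 0.19 (adjusted p = 4.71e-05). The adhesin gene HWP1 was not called, with a change of 0.21 ± 0.21 (adjusted p = 0.510). HYR1, UME6, HGC1 and the yeast wall protein gene YWP1 were not called either, with -0.64 ± 0.29, -0.65 ± 0.36, -0.09 ± 0.18 and 1.15 ± 0.44 (adjusted p = 0.121, 0.212, 0.753 and 0.0713). Of the 22 hypha-associated genes 3 rose and 8 fell, the same as adjusted over the list alone, and neither this list (median -0.43, camera adjusted p = 0.110) nor the 8 core hyphal genes (1 rose, 3 fell, median -0.37, camera adjusted p = 0.174) passed the test. Of the 21 regulators of filamentation 9 rose and 0 fell, or 9 and 1 adjusted over the list alone (median 0.48, camera adjusted p = 0.0111, adjusted p = 0.132 with an estimated correlation). Among them were NRG1, a repressor, and ROB1, a biofilm regulator (1.58 ± 0.51, adjusted p = 0.0335). Of the 12 yeast-form-associated genes 3 rose and 0 fell, or 5 and 0 adjusted over the list alone (median 0.43, camera adjusted p = 0.0284, adjusted p = 0.410 with an estimated correlation), with NRG1 again and RHD3, a cell wall protein gene, at 2.07 ± 0.28 (adjusted p = 9.17e-05).

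The lists for the mitochondrial ribosome, mitochondrial import and heat shock were called lower at 1 h, while those for the respiratory chain (median -0.09, camera adjusted p = 0.710) and the TCA cycle (median -0.20, camera adjusted p = 0.683) were not called. In the mitochondrial ribosome list 8 of 13 genes fell and 0 rose, or 12 and 0 adjusted over the list alone (median -1.24, camera adjusted p = 2.99e-05, adjusted p = 0.132 with an estimated correlation). MRPL3 changed by -2.69 ± 0.58 (adjusted p = 0.00356). MRP20 had 20 counts in DMSO against 3 in gladiolin, a log2 ratio of -2.75 with an exact binomial interval of -5.14 to -0.99 for counting error (edgeR log2 fold change -2.62, adjusted p = 0.0380). In the mitochondrial import and chaperone list 16 of 27 fell and 3 rose, or 16 and 4 adjusted over the list alone (median -0.72, camera adjusted p = 0.00158, adjusted p = 0.132 with an estimated correlation). TIM9 stood at -3.01 ± 0.63 and TOM7 at -2.49 ± 0.64 (adjusted p = 0.00297 and 0.0110). In the list of heat shock proteins and chaperones 8 of 20 fell and 2 rose, or 9 and 3 adjusted over the list alone (median -0.29, camera adjusted p = 0.0275, adjusted p = 0.148 with an estimated correlation). Its abundant Hsp70 gene SSA2 went from 8462 ± 950 to 2271 ± 545 CPM (-1.90 ± 0.20, adjusted p = 6.92e-06), and the co-chaperone gene STI1 changed by -1.60 ± 0.30 (adjusted p = 0.00126).

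The lists for the proteasome, ribosome biogenesis and RNA polymerase were called lower too, although most of their members were not called. Of 28 proteasome genes 5 fell and 0 rose, also adjusted over the list alone (median -0.39, camera adjusted p = 0.00244, adjusted p = 0.153 with an estimated correlation). The core subunit gene PRE2 stood at -1.63 ± 0.42 and PUP3 at -1.06 ± 0.30 (adjusted p = 0.0108 and 0.0185). Of 69 members of the ribosome biogenesis list, drawn mostly by name prefix, 7 fell and 2 rose, or 6 and 2 adjusted over the list alone (median -0.28, camera adjusted p = 0.0275, adjusted p = 0.550 with an estimated correlation). Without 12 members of other processes, 6 of 57 fell and 0 rose, or 2 and 0 adjusted over the list alone (median -0.28, camera adjusted p = 0.00970, adjusted p = 0.524 with an estimated correlation). MRT4 stood at -2.01 ± 0.59 and UTP4 at -1.35 ± 0.46 (adjusted p = 0.0216 and 0.0440). Of 14 subunits of the nuclear RNA polymerases 4 fell and 0 rose, the same adjusted over the list alone (median -0.64, camera adjusted p = 0.0412, adjusted p = 0.153 with an estimated correlation). RPC10 stood at -1.01 ± 0.16 and RPB8 at -0.93 ± 0.18 (adjusted p = 0.000389 and 0.00185). Of the genes with a symbol, at least 10 CPM and gladiolin libraries both below the DMSO libraries, those that fell most were KRE1, a cell wall glucan gene, at -3.06 ± 0.35, the mitochondrial matrix protein gene MAM33 at -2.84 ± 0.46 and CCC1, related to vacuolar iron transporters, at -2.73 ± 0.42. They were followed by the translation initiation factor gene SUI1 at -2.69 ± 0.53, the import chaperone gene TIM10 at -2.34 ± 0.42 and the sphingomyelinase-like gene ASM3 at -2.25 ± 0.36 (adjusted p = 1.93e-05 to 0.00173). Beside these falls, the share of counts on the 1739 genes too sparse to test was 0.292 ± 0.0352% in DMSO and 0.174 ± 0.00176% in gladiolin (SD, n = 2 each). This share, here and below, is of unscaled library totals, while the fold changes are TMM-scaled. Scaling by totals alone put the median of all tested genes at -0.45 at 1 h. Part of the difference in share may therefore be common to all genes. In 5 pooled lists of complexes (cytosolic and mitochondrial ribosome, respiratory chain, mitochondrial import and proteasome), the 64 members under 100 CPM had a median log2 fold change of -0.97. The 109 members at or above that level had one of 0.09. Of these, 61 encode cytosolic ribosomal proteins (median 0.18) and 20 belong to the respiratory chain (0.10). The abundant members of mitochondrial import had a median of -0.67 (7 of 11 fell, 2 rose). Those of the proteasome had -0.27 (2 of 16 fell, 0 rose), and the 1 of the mitochondrial ribosome stood at -0.83.

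In all, edgeR called 1113 of 4480 genes at 1 h, 574 higher and 539 lower, of which 652 changed at least 2-fold (356 higher, 296 lower). Without gladiolin 1 h replicate 1 or 2 the count was 678 or 513. Leaving out 1 of the 4 libraries ended the call for 10 of the 35 named genes called at 1 h, each of the 4 ending at least 1. The edgeR adjusted p reached 0.0518 for TIM9, 0.0545 for MRPL3, 0.0776 for AOX2, 0.104 for PRE2, 0.131 for TOM7, 0.134 for MRT4, 0.141 for PUP3, 0.226 for MRP20, 0.273 for UTP4 and 0.357 for ROB1. Fitting only the groups compared ended the calls of HTA2, MRP20, UTP4 and PUP3, and DESeq2 those of PUP3 and ROB1. Leaving out the filter ended that of UTP4. Library size alone ended that of ROB1 and called HYR1, HGC1 and UME6, while YWP1 was called without a filter or in a fit of only the groups compared. Refitted on genes of at least 100 CPM alone, the camera calls ended for mitochondrial import and for heat shock (adjusted p = 0.0545 each), the yeast-form list (0.0817), filamentation regulators (0.229), ribosome biogenesis and ergosterol (0.337 each) and RNA polymerase (0.519). The mitochondrial ribosome list could not be tested there, since 12 of its 13 members were below that level.

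**Figure D1:**
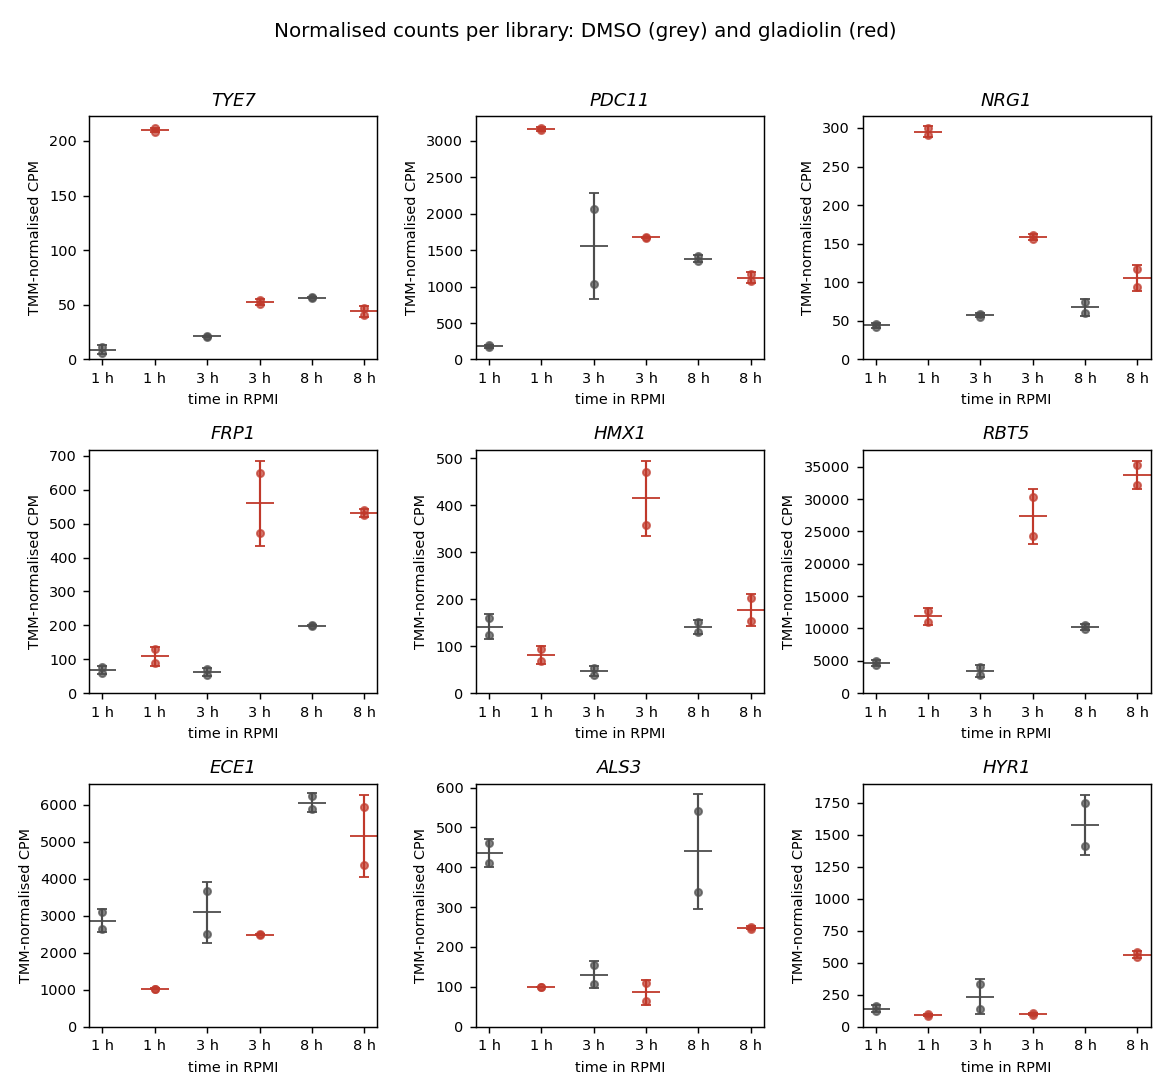
TMM-normalised CPM of 9 named genes in each library (points) with the group mean and SD (bars, n = 2), for DMSO in grey and gladiolin in red at 1, 3 and 8 h. TYE7, PDC11 and NRG1 stood apart most at 1 h (log2 fold changes 4.66, 4.12 and 2.73), FRP1, HMX1 and RBT5 at 3 h (3.20, 3.18 and 3.00), ECE1 and ALS3 were lower at 1 h (-1.48 and -2.12) and HYR1 at 8 h (-1.49).

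The second comparison asked what differed at 3 h. Iron acquisition genes rose most. FRP1 (orf19.5634), a ferric reductase-like gene, went from 61.7 ± 11.5 to 560.5 ± 125 CPM (log2 3.20 ± 0.24, adjusted p = 1.62e-06). HMX1 (orf19.6073), which encodes haem oxygenase, went from 46.6 ± 10.8 to 414.5 ± 79.8 CPM (3.18 ± 0.26, adjusted p = 3.62e-06). RBT5 (orf19.5636), the abundant CFEM haem receptor, went from 3416 ± 877 to 27334 ± 4269 CPM (3.00 ± 0.19, adjusted p = 3.89e-07). The related PGA7 rose by 3.16 ± 0.22 and CSA1 by 2.83 ± 0.24 (adjusted p = 7.74e-07 and 4.79e-06), and both may share reads with it. Of the 29 iron uptake and regulation genes 13 rose and 2 fell, or 16 and 3 adjusted over the list alone (median 1.04, camera adjusted p = 5.55e-08, adjusted p = 0.173 with an estimated correlation). MNN13, of a mannosyltransferase family, rose by 2.92 ± 0.46 (adjusted p = 0.00186) from 4 and 5 counts in the DMSO libraries to 36 and 44 in the gladiolin libraries.

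The lists for amino acid biosynthesis and cytosolic ribosomal proteins were called lower at 3 h, although most of their members were not called. Of the 40 amino acid biosynthesis genes 11 fell and 1 rose, or 16 and 1 adjusted over the list alone (median -0.61, camera adjusted p = 1.22e-07, adjusted p = 0.173 with an estimated correlation). LEU4, of leucine synthesis, changed by -2.43 ± 0.43 and GDH3, an NADP-dependent glutamate dehydrogenase gene, by -2.05 ± 0.26 (adjusted p = 0.00340 and 0.000442). MEP2, an ammonium permease, fell by 3.75 on the log2 scale (SE 0.54, adjusted p = 0.00109), from 25 and 48 counts to 3 and 3. Of the 71 cytosolic ribosomal protein genes 26 fell and 0 rose, or 35 and 0 adjusted over the list alone (median -0.51, camera adjusted p = 2.54e-13, adjusted p = 0.235 with an estimated correlation). RPS21 went from 3266 ± 668 to 1455 ± 120 CPM (-1.17 ± 0.17, adjusted p = 0.000972) and RPL82 from 680.7 ± 104 to 306.4 ± 23.0 CPM (-1.15 ± 0.16, adjusted p = 0.000814). ASM3 changed by -2.65 ± 0.36, the oxidoreductase-like gene CIP1 by -2.64 ± 0.62 and the mitochondrial carrier gene OAC1 by -2.06 ± 0.46 (adjusted p = 0.000713, 0.0146 and 0.0115). The share of counts on the untested sparse genes was 0.213 ± 0.0125% in DMSO and 0.214 ± 0.0129% in gladiolin at this time.

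Of the morphogenesis genes NRG1 was still higher at 3 h, at 57.1 ± 2.68 CPM in DMSO and 159.1 ± 3.73 in gladiolin (1.47 ± 0.19, adjusted p = 0.000493), and EFG1, a regulator of both growth forms, rose by 1.64 ± 0.37 (adjusted p = 0.0126). Of the 21 filamentation regulators 4 rose and 0 fell, or 5 and 1 adjusted over the list alone (median 0.46, camera adjusted p = 0.0373, adjusted p = 0.235 with an estimated correlation). In the yeast-form list 5 of 12 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.99, camera adjusted p = 0.00902, adjusted p = 0.346 with an estimated correlation). The chitinase gene CHT3 stood at 2.18 ± 0.51 and FGR41 at 1.74 ± 0.36 (adjusted p = 0.0146 and 0.00720). HYR1, a hyphal wall protein gene, fell by 1.27 on the log2 scale (SE 0.30, adjusted p = 0.0148). ECE1, ALS3, HWP1, HGC1, UME6 and YWP1 were not called, with changes of -0.31, -0.58, -0.08, -0.24, -0.61 and 0.09 (adjusted p = 0.321, 0.209, 0.873, 0.448, 0.329 and 0.936). AOX2 and ICL1 were likewise not called at -0.91 and 0.31 (adjusted p = 0.484 and 0.475). Of the 21 histone and S phase genes 3 rose, or 10 adjusted over the list alone, and 0 fell (median 0.34, camera adjusted p = 0.0221, adjusted p = 0.453 with an estimated correlation). HHT2 stood at 0.88 ± 0.15 and HHO1 at 0.73 ± 0.14 (adjusted p = 0.00271 and 0.00653). The glycolysis list was not called (median 0.08, mean near 0 and of negative sign, camera adjusted p = 0.751), with 1 gene higher and 2 lower, or 4 and 2 adjusted over the list alone.

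In all, edgeR called 386 genes at 3 h, 169 higher and 217 lower, of which 196 changed at least 2-fold (120 higher, 76 lower). The count was 155 without DMSO replicate 1, 152 without gladiolin replicate 1 and 74 without gladiolin replicate 2. Leaving out 1 of the 4 libraries ended the call for 8 of the 21 named genes called at 3 h, each of the 4 ending at least 1. The edgeR adjusted p then reached 0.0504 for LEU4, 0.0672 for FGR41, 0.0770 for HHO1, 0.0944 for EFG1, 0.125 for OAC1, 0.129 for CIP1, 0.132 for CHT3 and 0.218 for HYR1. Refitted on genes of at least 100 CPM alone, the camera calls of the yeast-form list (adjusted p = 0.189) and the filamentation regulators (adjusted p = 0.215) ended. Without members of other processes, an alternative chosen after the data were seen, 2 narrowed lists were called lower at 3 h, ribosome biogenesis and the proteasome. In ribosome biogenesis 3 of 57 fell and 0 rose, likewise adjusted over the list alone (median -0.30, camera adjusted p = 0.00999, adjusted p = 0.472 with an estimated correlation). In the proteasome 4 of 25 fell and 0 rose, or 5 and 0 adjusted over the list alone (median -0.33, camera adjusted p = 0.0236, adjusted p = 0.339 with an estimated correlation). With their full membership neither was called (camera adjusted p = 0.0850 and 0.0622).

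The third comparison concerned 8 h. The CFEM genes were again higher. CSA1 went from 122.7 ± 0.643 to 560.5 ± 55.4 CPM (log2 2.19 ± 0.21, adjusted p = 0.000111) and PGA7 from 1026 ± 12.7 to 3655 ± 111 CPM (1.83 ± 0.20, adjusted p = 0.000237). CSA2 rose by 2.61 ± 0.52 on the log2 scale (adjusted p = 0.0124), from 12 and 9 counts to 44 and 60. Reads may be shared within this family. Of the 29 iron genes 10 rose and 4 fell, or 14 and 5 adjusted over the list alone (median 0.44, camera adjusted p = 0.000293, adjusted p = 0.339 with an estimated correlation). SOU2, related to sorbose reductases, rose by 2.17 ± 0.51, the aquaporin gene AQY1 by 2.11 ± 0.43 and the heat shock gene HSP30 by 1.88 ± 0.34 (adjusted p = 0.0283, 0.0146 and 0.00987). The 69 members of the ribosome biogenesis list had a median of 0.31 and passed the list test (camera adjusted p = 0.000158, adjusted p = 0.460 with an estimated correlation), though 0 of them were called alone, also adjusted over the list alone. Without the 12 members of other processes the median was 0.41 (camera adjusted p = 1.07e-05, adjusted p = 0.461 with an estimated correlation), again with 0 called. The 9 members of at least 100 CPM had a median of 0.12, and refitted on genes of that level alone one of -0.03 (adjusted p = 0.923).

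The lists for the respiratory chain, cytosolic ribosomal proteins and ergosterol were called lower at 8 h, although most of their members were not called. Their sparsely counted members had the lower medians. Of the 34 genes of the respiratory chain and ATP synthase 6 fell and 0 rose, or 16 and 0 adjusted over the list alone (median -0.52, camera adjusted p = 9.13e-05, adjusted p = 0.264 with an estimated correlation). ATP7 and ATP18, subunits of the ATP synthase, changed by -2.44 ± 0.51 and -1.76 ± 0.37 (adjusted p = 0.0165 and 0.0191). Of the 71 cytosolic ribosomal protein genes 14 fell and 0 rose, or 16 and 0 adjusted over the list alone (median -0.21, camera adjusted p = 0.000111, adjusted p = 0.460 with an estimated correlation). RPS7A changed by -1.92 ± 0.31 and RPS17B by -1.77 ± 0.24 (adjusted p = 0.00465 and 0.00141). Of the 24 ergosterol genes 1 fell and 0 rose, or 3 and 0 adjusted over the list alone (median -0.31, camera adjusted p = 0.0286, adjusted p = 0.305 with an estimated correlation). The 1 called was ERG4, at -1.84 ± 0.45 (adjusted p = 0.0372). Beside these falls, the share of unscaled counts on the untested sparse genes was 0.422 ± 0.131% in DMSO and 0.250 ± 0.0101% in gladiolin. Scaling by totals alone put the median of all tested genes at -0.19 at 8 h, so part of this difference may again be common to all genes. The 10 ribosomal protein genes under 100 CPM had a median of -1.29 (7 fell) and the 61 more abundant ones one of -0.18 (7 fell). For the respiratory chain the medians were -1.27 (14 genes, 5 fell) and -0.15 (20 genes, 1 fell). Refitted on genes of at least 100 CPM alone, both lists still passed, at medians of -0.33 and -0.29 (camera adjusted p = 8.61e-12 and 0.000932), and the ergosterol list did not (adjusted p = 0.489).

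Hyphal genes were partly lower at 8 h. HYR1 (orf19.4975) went from 1577 ± 236 to 560.8 ± 27.8 CPM (-1.49 ± 0.28, adjusted p = 0.0103) and UME6, the regulator of hyphal extension, from 48.0 ± 17.7 to 20.4 ± 5.89 CPM (-1.28 ± 0.32, adjusted p = 0.0398). AOX2 went from 136.6 ± 86.5 to 37.6 ± 7.25 CPM (-1.88 ± 0.42, adjusted p = 0.0228). HWP1, ECE1, ALS3 and HGC1 were not called, at 0.18 ± 0.21, -0.23 ± 0.18, -0.83 ± 0.25 and -0.25 ± 0.18 (adjusted p = 0.701, 0.515, 0.0722 and 0.470). NRG1, YWP1 and ICL1 were not called at 0.66 ± 0.19, -0.80 ± 0.47 and 0.33 ± 0.27 (adjusted p = 0.0603, 0.362 and 0.530). The hypha-associated list did not pass (2 of 22 rose and 3 fell, or 2 and 5 adjusted over the list alone, median -0.24, camera adjusted p = 0.334). The largest falls were RTA4, of a lipid transporter-like family, at -3.42 ± 0.54 (53 and 29 counts against 4 and 2), the mannosyltransferase-family gene MNN15 at -2.71 ± 0.41, CIP1 at -2.65 ± 0.47, ATP7, ASM3 at -2.42 ± 0.34 and the phosphatase gene PTP3 at -2.21 ± 0.33 (adjusted p = 0.00165 to 0.0165).

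Calls at 8 h differed with abundance. Of the 896 most abundant genes 45 were higher and 14 lower (median log2 fold change 0.11), and of the 896 least abundant 1 and 13 (-0.67). The groups of 896 genes between them had 8, 9 and 10 higher and 23, 26 and 25 lower, in order of rising abundance. Part of the lower calls may therefore follow abundance, and the size of that part was not tested. In all, edgeR called 174 genes at 8 h, 73 higher and 101 lower. Of these 121 changed at least 2-fold (34 higher, 87 lower). The count was 95 when only the 4 libraries compared were fitted. The count was 28 without DMSO replicate 1, 343 without DMSO replicate 2, 35 without gladiolin replicate 1 and 21 without gladiolin replicate 2. Of the 19 named genes called at 8 h, CSA1, PGA7, MNN15, ASM3 and RPS17B were called in each of the 4 fits that left out 1 library. The other 14 were not in at least 1 of them, each library but DMSO replicate 2 ending several. The edgeR adjusted p reached 0.0589 for RPS7A, 0.0919 for CSA2, 0.0969 for PTP3, 0.112 for HSP30, 0.113 for RTA4, 0.144 for HYR1, 0.173 for CIP1, 0.197 for ATP7, 0.215 for ATP18, 0.278 for SOU2, 0.311 for AQY1, 0.328 for AOX2 and for ERG4 and 0.354 for UME6. Fitting only the groups compared ended the calls of SOU2, UME6 and ERG4, and DESeq2 that of UME6. ALS3 was called with library size alone, and ALS3 and YWP1 without DMSO replicate 2.

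**Figure D2:**
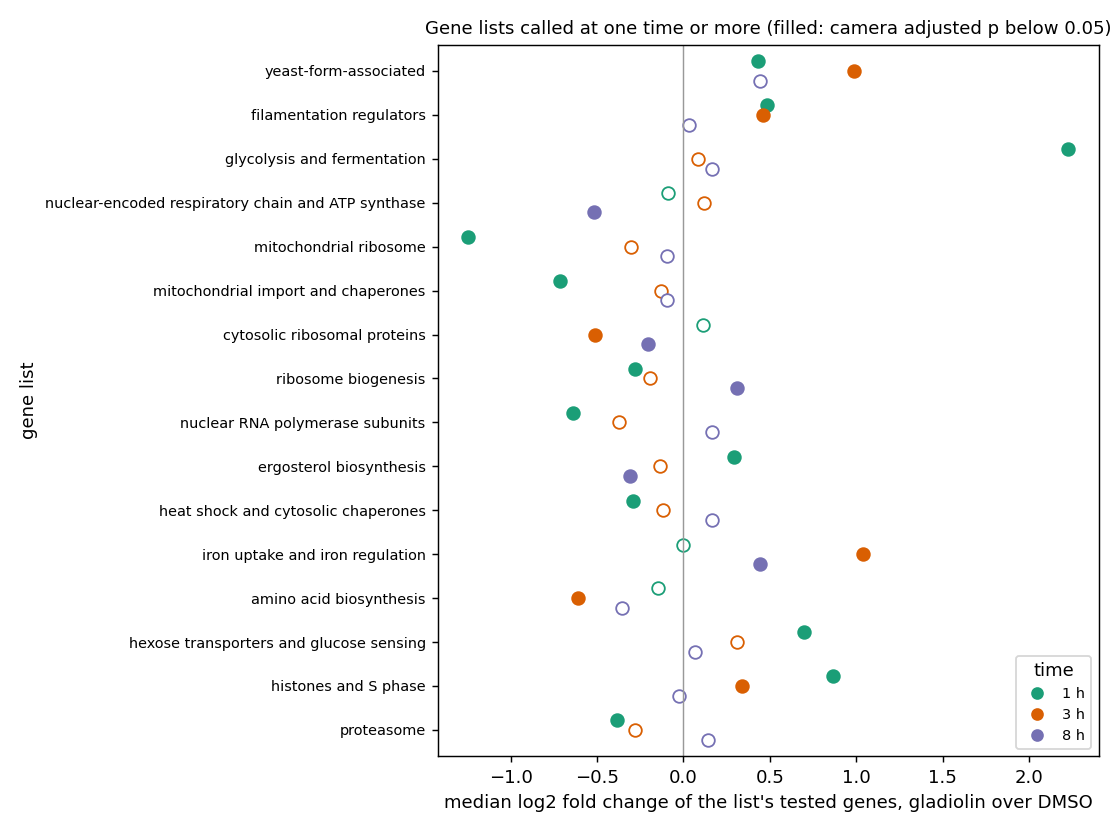
Median log2 fold change (gladiolin over DMSO) of the tested genes of each list called at 1, 3 or 8 h, with filled circles for a camera adjusted p below 0.05 and open circles otherwise. The glycolysis list stood at 2.23 at 1 h and 0.08 at 3 h, the iron uptake list at 1.04 at 3 h, and the ergosterol list at 0.29 at 1 h, a sign that turns when libraries are scaled by their totals alone.

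**Figure D3:**
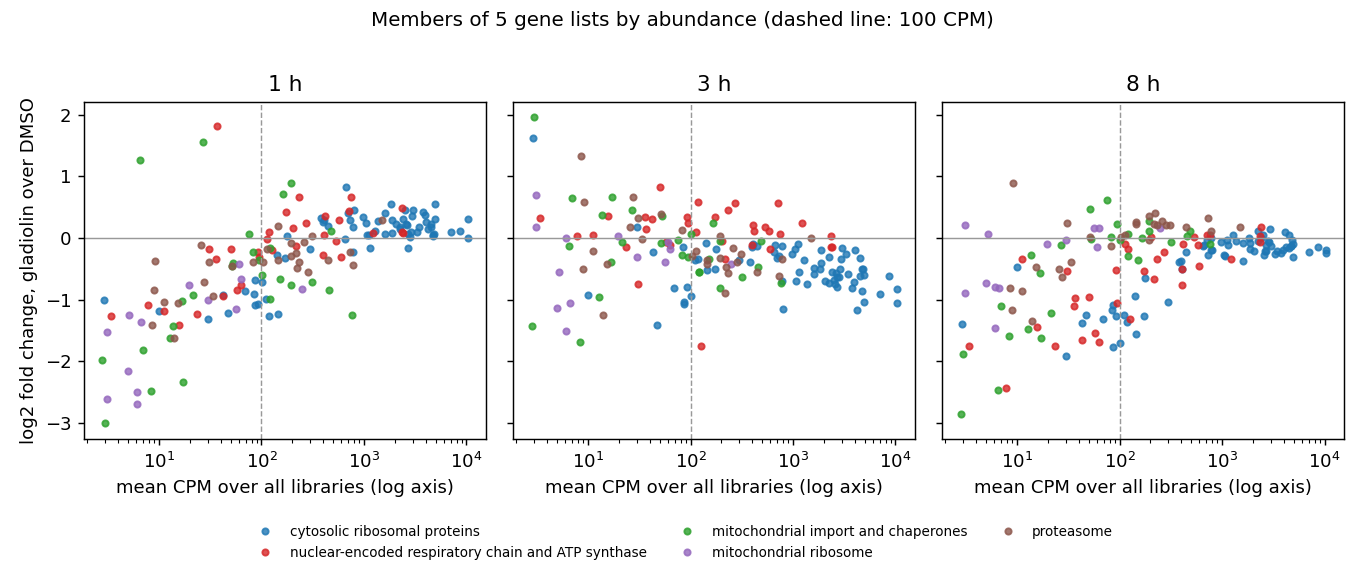
Log2 fold change (gladiolin over DMSO) of each tested member of 5 gene lists (points, coloured by list) against its mean CPM over the 12 libraries on a log axis, at 1, 3 and 8 h, with a dashed line at 100 CPM. Pooled over the 5 lists, the medians left and right of the line were -0.97 and 0.09 at 1 h, -0.07 and -0.36 at 3 h, and -0.88 and -0.10 at 8 h. Cytosolic ribosomal proteins make up 61 of the 109 genes on the right.

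The fourth comparison tested whether the response to gladiolin differed between times. From 1 to 3 h the glycolysis response shrank, with a median difference of -2.15 over the list (17 of 20 genes lower, or 20 adjusted over the list alone, camera adjusted p = 4.88e-25, adjusted p = 0.0187 with an estimated correlation). HGT7 changed by -4.03 (adjusted p = 3.47e-07) and PDC11 by -4.01 (adjusted p = 1.59e-06). The iron list was not called at 1 h, where 9 of 29 genes rose and 7 fell, also adjusted over the list alone. Its median there was -7.5e-04 (camera adjusted p = 0.710, adjusted p = 0.869 with an estimated correlation). From 1 to 3 h its response moved up by a median of 1.15 (12 genes higher and 2 lower, or 16 and 2 adjusted over the list alone, camera adjusted p = 2.43e-07, adjusted p = 0.110 with an estimated correlation). HMX1 moved by 3.97 (adjusted p = 2.03e-06) and FRP1 by 2.51 (adjusted p = 0.000120). The response of the ribosomal protein genes moved down by a median of -0.55 (21 of 71 lower, or 32 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.32e-07, adjusted p = 0.303 with an estimated correlation). That of the hypha-associated genes moved up by 0.54 (6 of 22 higher, or 8 adjusted over the list alone, camera adjusted p = 0.00533, adjusted p = 0.207 with an estimated correlation), with ECE1 at 1.17 and ALS3 at 1.54 (adjusted p = 0.0124 and 0.0165). The response of NRG1 was smaller at 3 h than at 1 h by -1.26 (adjusted p = 0.00685). From 3 to 8 h the responses of HMX1 and FRP1 shrank by -2.83 and -1.78 (adjusted p = 0.00281 and 0.0186). The iron list had a median of -0.53 (4 of 29 lower, or 5 adjusted over the list alone, camera adjusted p = 0.00353, adjusted p = 0.342 with an estimated correlation). In all, edgeR called 383 genes (107 higher, 276 lower) between 1 and 3 h and 78 (43 higher, 35 lower) between 3 and 8 h. The first count was 225 and 180 without gladiolin 1 h replicate 1 and 2, and 226 and 146 without gladiolin 3 h replicate 1 and 2. The second was 14 and 153 without DMSO 3 h replicate 1 and 2, 4 and 1 without gladiolin 3 h replicate 1 and 2, 29 and 120 without DMSO 8 h replicate 1 and 2, and 0 and 10 without gladiolin 8 h replicate 1 and 2. This compares with 863 genes at an unadjusted p under 0.05 with all libraries and 209 calls with DESeq2.

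The genes called at different times overlapped, and no libraries are shared between these comparisons. At 1 and 3 h 86 genes were higher at both times, where 21.7 would be shared by independent lists, and 67 were lower at both against 26.1. At 3 and 8 h 28 were higher at both against 2.75, and 17 lower against 4.89. At 1 and 8 h 34 were higher at both against 9.35, and 51 lower against 12.2. The numbers for independent lists take no account of gene abundance, on which calls may depend. Over the 4480 genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.28 for 1 and 3 h, 0.19 for 3 and 8 h and 0.32 for 1 and 8 h. The 896 least abundant genes had median log2 fold changes of -0.31, 0.06 and -0.67 at 1, 3 and 8 h. The 896 most abundant had 0.12, -0.17 and 0.11. Part of the overlap and correlation at 1 and 8 h may therefore follow abundance, and its size was not tested. ASM3 was lower at each of the 3 times, and NRG1 was called higher at 1 and 3 h.

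The fifth comparison described the solvent control over time. From 1 to 3 h in DMSO the translation genes fell. Of the 71 cytosolic ribosomal protein genes 68 fell and 0 rose, or 69 and 0 adjusted over the list alone (median -1.39, camera adjusted p = 1.09e-25, adjusted p = 0.0934 with an estimated correlation). Of the 69 members of the ribosome biogenesis list 41 fell and 1 rose, or 46 and 1 adjusted over the list alone (median -1.11, camera adjusted p = 4.25e-09, adjusted p = 0.195 with an estimated correlation). Without the 12 members of other processes 40 of 57 fell and 0 rose, or 45 and 0 adjusted over the list alone (median -1.19, camera adjusted p = 1.94e-11, adjusted p = 0.193 with an estimated correlation). Glycolysis genes rose over the same interval, 17 of 20 with 0 lower, or 18 and 0 adjusted over the list alone (median 1.69, camera adjusted p = 1.91e-13, adjusted p = 0.0934 with an estimated correlation). So did 12 of 18 hexose transporter genes with 2 lower, the same adjusted over the list alone (median 0.81, camera adjusted p = 0.00597, adjusted p = 0.195 with an estimated correlation). Of 26 oxidative stress genes 14 rose and 4 fell, or 15 and 4 adjusted over the list alone (median 0.84, camera adjusted p = 0.00628, adjusted p = 0.0934 with an estimated correlation). HGC1, the hypha-specific cyclin gene, rose by 1.39 ± 0.18 (adjusted p = 3.27e-05), AOX2 by 3.26 ± 0.87 (adjusted p = 0.00925) and UME6 by 1.00 ± 0.35 (adjusted p = 0.0351), while ALS3 changed by -1.76 ± 0.26 (adjusted p = 8.67e-05). HWP1, ECE1, HYR1, NRG1, YWP1 and ICL1 were not called, at -0.13, 0.11, 0.75, 0.37, 0.41 and -0.14 (adjusted p = 0.686, 0.679, 0.0528, 0.149, 0.557 and 0.683). HYR1 was called with RLE factors, with DESeq2, without a filter, with the replicate block and without DMSO 3 h replicate 1.

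From 3 to 8 h in DMSO hyphal and iron genes rose. HYR1 rose by 2.72 ± 0.29 (adjusted p = 5.39e-05), ALS3 by 1.77 ± 0.26 (adjusted p = 0.000356), UME6 by 1.27 ± 0.32 (adjusted p = 0.0109), ECE1 by 0.97 ± 0.18 (adjusted p = 0.00208) and HWP1 by 0.70 ± 0.22 (adjusted p = 0.0285). Of the 22 hypha-associated genes 13 rose and 1 fell, or 13 and 2 adjusted over the list alone (median 0.79, camera adjusted p = 0.00127, adjusted p = 0.181 with an estimated correlation). Of the 29 iron genes 17 rose and 0 fell, or 18 and 0 adjusted over the list alone (median 0.91, camera adjusted p = 1.18e-05, adjusted p = 0.181 with an estimated correlation). AOX2 rose by 3.94 ± 0.51 (adjusted p = 0.000159), ICL1 changed by -1.01 ± 0.26 (adjusted p = 0.0120), and HGC1, NRG1 and YWP1 were not called at -0.08, 0.24 and 0.97 (adjusted p = 0.774, 0.401 and 0.158). Of the ribosomal protein genes 32 rose and 0 fell, or 37 and 0 adjusted over the list alone (median 0.47, camera adjusted p = 2.20e-07, adjusted p = 0.284 with an estimated correlation), with a median of 2.07 in the 10 sparse and 0.42 in the 61 abundant members. The share of unscaled counts on the untested sparse genes was 0.213% at 3 h and 0.422% at 8 h.

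In all, edgeR called 1620 genes from 1 to 3 h in DMSO (822 higher, 798 lower; at least 2-fold 479 higher, 527 lower) and 1119 from 3 to 8 h (608 higher, 511 lower; at least 2-fold 509 higher, 150 lower). The second count was 715 and 740 without DMSO 3 h replicate 1 and 2, 585 without DMSO 8 h replicate 1, 587 when only the groups compared were fitted and 733 with the strict filter. From 1 to 3 h leaving out 1 library ended the calls of UME6 (each of the 4 libraries, adjusted p up to 0.132) and AOX2 (DMSO 1 h replicate 2 or 3 h replicate 1, up to 0.139). From 3 to 8 h it ended those of HWP1 (3 h replicate 1 or 8 h replicate 2, up to 0.255), UME6 (3 h replicate 2 or 8 h replicate 1, up to 0.131) and ICL1 (8 h replicate 2, 0.0836). Fitting only the groups compared ended the calls of UME6 from 1 to 3 h and of HWP1 and ICL1 from 3 to 8 h. Library size alone ended those of UME6 and ICL1, and DESeq2 that of UME6. YWP1 was called from 3 to 8 h without DMSO 8 h replicate 2.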

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

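The tests of counting noise, of the 3 complexes, of library scaling, of the DMSO time course (with shared and separate controls), of paralogs and of iron-using genes at 8 h (all and abundant) were chosen only after the results were seen, and the bound of the test of iron-using genes at 3 h was changed after it. The genes and lists in the next 3 paragraphs stand out because their response to gladiolin differed between times by an interaction test in edgeR or camera with adjusted p below 0.05, and the values are differences of log2 fold changes.

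From 1 to 3 h the response changed by -4.01 for HGT6, -3.35 for TYE7, -4.22 for YHB1, -4.03 for HGT7, -3.19 for CDR4, -4.01 for PDC11 and -4.14 for RNR22. The changes were -3.65 for PGA10, -4.12 for AOX2, -2.50 for ERG251, -3.46 for ERG1, -1.26 for NRG1, -1.31 for RPS21 and -1.60 for RPL82. It rose by 3.97 for HMX1, 2.51 for FRP1, 1.66 for PGA7, 1.65 for RBT5, 1.41 for CSA1, 2.67 for MNN13 and 1.75 for FGR41. It also rose by 1.17 for ECE1, 1.54 for ALS3, 0.97 for SSA2, 3.01 for TIM10 and 4.96 for TIM9. The TIM9 value rests on 1 count in DMSO and 5 in gladiolin at 3 h, a log2 ratio of 2.12 with an exact interval of -1.04 to 7.68.

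Lists whose response differed from 1 to 3 h had median differences of -2.15 (glycolysis and fermentation), 1.15 (iron uptake), -0.55 (cytosolic ribosomal proteins), -0.57 (amino acid biosynthesis), 0.77 (mitochondrial ribosome), -0.55 (histones and S phase), 0.54 (hypha-associated), -0.56 (ergosterol) and 0.58 (cell wall damage response). The first had adjusted p = 0.0187 with an estimated correlation and the others adjusted p from 0.110 to 0.336.

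From 3 to 8 h the response changed by -1.65 for TYE7, -1.43 for YHB1, 1.04 for RPC10, -1.78 for FRP1, -2.83 for HMX1, -1.33 for PGA7, -1.27 for RBT5, -3.27 for MNN13, 3.69 for MEP2, 1.02 for RPS21 and 0.96 for RPL82. For lists the medians were -0.68 (respiratory chain and ATP synthase), 0.30 (cytosolic ribosomal proteins), 0.58 (ribosome biogenesis), 0.48 (nuclear RNA polymerase subunits), 0.34 (heat shock), -0.53 (iron uptake), 0.27 (amino acid biosynthesis), -0.60 (sulphur amino acids) and -0.56 (histones and S phase). Adjusted p ran from 0.213 to 0.566 with an estimated correlation. Leaving out single libraries moved the number of genes called here between 0 (without gladiolin 8 h replicate 1) and 153 (without DMSO 3 h replicate 2).

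The first pattern weighed is that sparsely counted members of complexes were lower under gladiolin at 1 h and 8 h (medians -0.97 and -0.88) while abundant members were near 0 (0.09 and -0.10). A downward bias of low counts at every time is argued against by 3 h, where the same 64 genes had a median of -0.067 (95% interval -0.18 to 0.14). Random counting noise predicts a median near 0, so the value at 3 h cannot decide on it. In DMSO these genes had median changes of -1.09 from 1 to 3 h and 1.16 from 3 to 8 h, so both 3 h groups were low. The 109 abundant members had -1.01 and 0.10, so when pooled only the later change set the sparse members apart. Of the 109, 61 encode ribosomal proteins, with -1.34 from 1 to 3 h against -2.58 in the 10 sparse ones. Within each of the lists the sparse members had the lower median from 1 to 3 h, for the proteasome -0.88 against -0.07. A fall of similar size in the whole complex at 8 h is argued against for ribosomal proteins (abundant median -0.18, -0.21 to -0.13, sparse -1.29) and the respiratory chain (-0.15, -0.40 to -0.03, sparse -1.27), though smaller falls remain, and for mitochondrial import at 1 h it cannot be told apart (-0.67, -0.84 to 0.11, sparse -0.98). Of the 2 DMSO 8 h libraries the one with more counts on untested genes (0.515% against 0.330%) had sparse members higher by 0.48 (0.31 to 0.61, over genes) relative to abundant ones, but both values measure nearly the same thing, in 1 pair of libraries. A varying share of reads away from the main 3′ ends and a rise of weakly expressed transcripts in DMSO therefore both stay open.

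The second pattern is the rise of the glycolysis list at 1 h. Library scaling is argued against by the lowest median over 3 scalings, 1.84, and a rise of abundant genes as a class by 10000 lists matched on abundance, of which the highest median was 0.69 against 2.23. Of its 20 genes 17 were called higher both at 1 h and in DMSO from 1 to 3 h, and over 1233 abundant genes the covariance of both changes was 0.42 against 0.0245 ± 0.00179 (SD, 50 simulations) from the shared DMSO 1 h libraries alone, an excess of 0.40 (correlation 0.51, simulated 0.49). With a separate DMSO 1 h library for each change the covariance was 0.35 and 0.41, so the response may in part be a change that DMSO cells make later. A full shift of the library to the 3 h state is argued against by the abundant ribosomal protein genes. Their median was 0.18 (0.09 to 0.24, over genes) under gladiolin and -1.34 in DMSO from 1 to 3 h. The sign under gladiolin may depend on scaling. Ribosomal protein genes held 445070 of 1765048 and 930433 of 3585677 counts in DMSO at 1 h. In gladiolin they held 793237 of 3460733 and 782053 of 3632697, a lower share. In DMSO at 3 h they held 101858 of 1034292 and 164140 of 1703833, lower still. A smaller shift therefore stays open.

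The third pattern is the rise of iron uptake genes at 3 h and 8 h. In DMSO the 17 sparse and 12 abundant members had medians of -0.48 and -0.39 from 1 to 3 h. From 3 to 8 h they had 0.91 and 1.02. The response at 3 h was thus measured against a low point of the control, and how much this adds was not tested. Reads shared within the CFEM family are argued against by 10 list members outside it that were called higher at 3 h and 6 at 8 h, and library scaling at 3 h by the lowest median over 3 scalings, 0.99, while at 8 h that median was 0.29 and scaling stays open as a part of the rise. A response like that to iron shortage may include lower levels of iron-using genes, and at 3 h their median of 0.21 (-0.31 to 0.34, 22 genes) leaves this open, with a sign opposite to camera's direction. At 8 h the 22 genes had a median of -0.75 (camera p = 1.41e-09, p = 9.81e-04 with an estimated correlation) and their 8 abundant members one of -0.56 (-0.77 to -0.51), which is consistent with it. Of the 22 genes 14 belong to the amino acid, ergosterol, respiratory or TCA cycle lists, and the other 8 had a median of -0.88, but 6 of these are sparsely counted and fall under the first pattern, and no iron level was measured.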

How the results depend on the processing

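Thinning to the smallest total, the fit of genes with at least 100 CPM and the lists without symbols of other function were chosen only after the data were seen. Counts with RLE factors, no filter and thinning stayed within 1.5 times, and thinning gave 758, 321 and 168 genes at 1, 3 and 8 h. With library size alone the counts were 1791 at 1 h (19.3% higher against 51.6%) and 631 for the change from 1 to 3 h (81.6% against 27.9%). It also moved the share of higher calls to 17.7% at 8 h (42.0% with TMM), 23.4% for the change from 3 to 8 h (55.1%), 36.2% for DMSO from 1 to 3 h (50.7%) and 81.6% from 3 to 8 h (54.3%). These splits follow the shift of the median of all genes, -0.45, 0.46, -0.19, -0.29, -0.25 and 0.36 in that order, which this scaling leaves in. With RLE factors 66.7% of the calls from 3 to 8 h were higher. DESeq2 gave 209 there (79.4% higher) and 16.1% higher calls from 1 to 3 h, and the cause was not tested. Fits of only the groups compared gave 95 at 8 h, 33 for the change from 3 to 8 h and 587 for DMSO from 3 to 8 h, with fewer libraries to estimate the spread. The strict filter gave 733 for the last, with 2947 genes tested. Genes of at least 100 CPM, 1233 in all, gave 537 at 1 h, 66 at 8 h, 753 and 362 for DMSO. The 2-fold threshold, stricter by construction, gave 652, 196, 1006 and 659 at 1 h, 3 h and in DMSO. Of 66 list calls 2 held with an estimated correlation. On genes of at least 100 CPM 42 were made, 33 of them shared, with 3 calls of the mitochondrial ribosome not testable there. The other 30 of the 66 ended, some of them in the interaction or DMSO comparisons. Library size alone ended 2 list calls, leaving out the filter 4 and thinning 5. Without symbols of other function 70 list calls were made, the 66 and 4 more. These were, at 3 h, ribosome biogenesis (-0.30, camera adjusted p = 0.00999), the proteasome (-0.33, 0.0236) and the TCA cycle (-0.12, 0.0396), and for the change from 3 to 8 h the proteasome (0.31, 0.0356). With an estimated correlation none of them was called (camera adjusted p = 0.472, 0.339, 0.448 and 0.421 in that order). Of the TCA cycle genes 4 of 17 fell, and of the proteasome genes from 3 to 8 h 0 of 25 were called alone.

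Leaving out 1 library, where the lone library is assumed to vary like the other groups, gave 513 to 1066 genes at 1 h, 74 to 367 at 3 h, 21 to 343 at 8 h, 146 to 463 for the change from 1 to 3 h, 0 to 153 from 3 to 8 h, 1174 to 1489 for DMSO from 1 to 3 h and 585 to 989 from 3 to 8 h. The calls of named genes numbered 73 to 86, newly made ones included, and of the 86 with all libraries 73 to 83 were kept. Fewer libraries lower the power, but 4 higher counts do not follow from that and the cause was not tested, namely 343 at 8 h and 120 for the change from 3 to 8 h without DMSO 8 h replicate 2, 463 for the change from 1 to 3 h without DMSO 1 h replicate 2 and 153 for the change from 3 to 8 h without DMSO 3 h replicate 2. Signs turned for genes that were not called. With library size alone HWP1 was -0.18 and ICL1 -0.0648 at 1 h, and in DMSO ECE1 was -0.0817 from 1 to 3 h and HGC1 0.20 from 3 to 8 h. Leaving out 1 library gave HGC1 -0.20 to 0.0358 at 1 h. At 3 h it gave HWP1 -0.38 to 0.30, YWP1 -0.35 (and -0.24) to 0.54 and AOX2 -1.74 to 0.13. At 8 h it gave HWP1 -0.0676 to 0.49, YWP1 -1.41 to 0.35 and ICL1 -0.0679 to 0.76. In DMSO from 1 to 3 h it gave HWP1 -0.48 to 0.18 (and 0.03), ECE1 -0.17 to 0.36, HYR1 -0.0232 to 1.23 and YWP1 -0.0370 to 0.86, and from 3 to 8 h YWP1 -0.17 to 1.58. Of 1156 other values of named genes 1014 kept their sign and side of the threshold, 110 lost the call and 14 gained it.

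With the replicate number as a replicate block edgeR called 1207, 417 and 184 genes at 1, 3 and 8 h, 403 and 93 for the changes from 1 to 3 h and from 3 to 8 h, and 1666 and 1150 in DMSO. It called 66 lists and 87 named genes, and ended no call of a list or named gene, while HYR1 in DMSO from 1 to 3 h gained one. Over the 15 pairs of groups the deviations of libraries with the same number had correlations of -0.17 to 0.23. The 3 above 0.1 were those among the DMSO groups, 0.23 for 1 and 3 h, 0.13 for 1 and 8 h and 0.11 for 3 and 8 h, so a weak link of the DMSO libraries by number stays open. Between treatments at 1, 3 and 8 h they were 0.01, -0.03 and -0.05, and the numbers were not used to pair samples.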

Other observations

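Further lists changed in the solvent control. From 1 to 3 h in DMSO, 15 of 34 respiratory chain genes fell and 0 rose (median -0.58, camera adjusted p = 0.00879, adjusted p = 0.195 with an estimated correlation). Of 14 RNA polymerase subunits 8 fell and 1 rose (median -0.92, camera adjusted p = 0.00597, adjusted p = 0.0934 with an estimated correlation). Of 29 iron genes 10 fell and 0 rose (median -0.44, camera adjusted p = 0.00879, adjusted p = 0.222 with an estimated correlation). The lists for the mitochondrial ribosome, mitochondrial import, amino acid synthesis, histones and S phase, mitosis and the proteasome were also called lower, at medians of -1.10, -0.54, -0.52, -0.42, -0.65 and -0.34 (camera adjusted p = 0.00879, 0.0112, 0.0112, 0.0352, 0.0272 and 0.0184). With an estimated correlation their adjusted p was 0.218, 0.195, 0.222, 0.379, 0.222 and 0.222. Adjusted over the list alone the counts were the same for the respiratory chain, RNA polymerase and iron lists. The share of unscaled counts on untested genes went from 0.292% to 0.213% over this interval.

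From 3 to 8 h in DMSO, 10 of 24 mitosis and cytokinesis genes rose and 0 fell (median 1.04, camera adjusted p = 0.000704, adjusted p = 0.181 with an estimated correlation). In addition, 9 of 21 histone and S phase genes rose with 0 lower (median 0.43, camera adjusted p = 0.0116, adjusted p = 0.364 with an estimated correlation). Several lists of carbon metabolism were called lower. Of 21 genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation 9 fell and 0 rose (median -0.84, camera adjusted p = 2.46e-05, adjusted p = 0.181 with an estimated correlation). Of 18 hexose transporter genes 9 fell and 0 rose (median -0.72, camera adjusted p = 3.48e-05, adjusted p = 0.181 with an estimated correlation). Of 20 glycolysis genes 10 fell and 3 rose (median -0.46, camera adjusted p = 0.00611, adjusted p = 0.284 with an estimated correlation). Amino acid synthesis, the TCA cycle and heat shock were called lower at medians of -0.40, -0.43 and -0.33 (camera adjusted p = 0.000307, 0.0401 and 0.0461). With an estimated correlation their adjusted p was 0.181, 0.364 and 0.181. Adjusted over the list alone the counts were 12 and 0 for mitosis, 9 and 1 for histones, 0 and 9 for gluconeogenesis, 0 and 10 for hexose transporters and 3 and 11 for glycolysis, risers first. The lists for phosphate acquisition, opaque-cell markers, drug efflux, actin and polarity, alternative respiration, the unfolded protein response and core hyphal genes were called in none of the 7 comparisons, with 3 to 32 tested members each.

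The glucose response at 1 h can be set against later DMSO cells, a comparison chosen only after the first results were seen. Among 1233 genes of at least 100 CPM, 185 were higher both under gladiolin at 1 h and in DMSO from 1 to 3 h, against 101.5 for independent lists, and 69 were lower in both against 36.4. Both comparisons use the same DMSO 1 h libraries, so part of this excess may come from them. With 1 separate DMSO 1 h library for each comparison, the lone library taken to vary like the other groups, 149 were higher in both either way round, against 92.8 and 72.5 for independent lists, and 54 and 44 were lower in both, against 34.1 and 21.1. The covariance of the changes, 0.40 above the simulated one with shared controls (correlation 0.51, simulated 0.49), was 0.35 and 0.41 with separate ones. Gladiolin libraries at 1 h exceeded DMSO libraries at 3 h by a median of 0.56 in the glycolysis list, 0.83 in the iron list and 1.53 in the ribosomal protein list. They were lower by median in the hexose transporter list (-0.20) and the core hyphal list (-0.65).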
